A study of Arabidopsis thaliana with 25 samples.

How the data were processed

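RNA was compared on 25 two-colour cDNA arrays from Arabidopsis thaliana. Each array set RNA of plants over-expressing a haemoglobin gene against RNA of transgenic control plants carrying the empty vector, in roots or shoots, after hypoxic stress or without it. The over-expressed gene was GLB1, the class 1 haemoglobin, or HE7L, a mutated form of it. Per the labels, the authors applied a spatial normalization within each array, and the deposited values are log ratios of both channels. The deposited values, spatially normalized by the authors, were read as log2 ratios, since the base of the logarithm is not given in the sources used here; log2 is the convention of the field, and every fold below rests on that reading. A base of 10 does not hold, since the largest value had a size of 5.80, beyond what scanner intensities can reach on that scale, while a natural logarithm is not excluded. Background correction and spot filters are not given in the sources used here. The median of every array was 0 as deposited, and no further centring or scaling was applied.

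The labels carry a dye swap flag per array. Arrays of the same group with opposite flags were compared over all probes: their median correlation across 18 pairs was -0.153 as deposited and 0.153 after turning the arrays of 1 flag, and 13 of the 18 pairs lay below 0 as deposited. Of 1802 probes with a nonzero value on every array, 0 had the same sign on all arrays as deposited and 13 did after turning, all of them above 0. Values were therefore turned to over-expressor over empty vector by the flag, the reading chosen by a rule set before the data were examined. That rule looked first to the probe of GLB1, but 0 probes name GLB1, GLB2 or GLB3, so the over-expressed transcripts were not analysed here. The overall sign is not settled: it follows the labelled channels and no value tests it. If it were the other way, every higher would read as lower. In the direction used, 7 pairs of arrays correlated below -0.3 over all probes, 2 of them of the same flag: HE7L shoots replicates 1 and 3 (r = -0.373) and HE7L hypoxic roots replicate 1 with GLB1 roots replicate 2 (r = -0.366). The pairs of opposite flag added HE7L shoots replicate 4, HE7L hypoxic shoots replicate 2 and GLB1 hypoxic shoots replicate 2, and the pair of GLB1 roots was taken as merged. Only HE7L shoots replicate 1 with replicates 3 and 4 were pairs within a group. All other pairs crossed groups, whose log ratios need not correlate. The mirror-image arrays of GLB1 roots each gave a pair with HE7L hypoxic roots replicate 1. The correlations over all probes leave the direction of these 7 arrays open, and values with each of them turned are given too. In the direction used AT5G56070, AT3G12000, AT5G56100, RR22 and AT3G02840 each lay above 0 on these arrays, AT5G56070 between 1.52 and 2.53. A turn acts on every probe of an array, so it would place these genes below 0 there, against all other arrays. These values argue against a wrong sign of these 7 arrays relative to the others. Results with an array turned therefore show how far a result rests on that array. A call of theirs lost with an array turned therefore does not show that the gene did not change.

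GLB1 roots replicates 2 and 3 were mirror images of each other, with a correlation of -0.9998 as deposited and 98.9% of probes equal in size within 0.01. They were averaged and counted as 1 replicate, a choice made after the values were seen, which left 24 arrays in the fit and 2 replicates for GLB1 roots. For HE7L arrays the source name of the over-expressor channel reads as wild-type GLB1, against the sample titles; the titles were followed. Replicate numbers were taken as not pairing arrays across groups, since no comparison had at least 3 pairs with every correlation over 0.1. HE7L minus GLB1 in roots had 1 such pair, and hypoxic minus not hypoxic had 1 in GLB1 roots and 2 in HE7L roots. These could not meet the rule, so pairing was not tested there.

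Of 13824 probes, 6495 named 1 gene and 7329 named none. Gene symbols and coordinates came from the TAIR10.1 annotation. Probes of the same gene were averaged per array with limma (version 3.58.1, R 4.3.3), giving 5258 named genes, 846 of them with over 1 probe; unnamed probes were tested singly. A gene entered a comparison with values on at least 2 arrays of each group in it. A linear model with 8 group coefficients and 1 dye term per gene was fitted to all 24 arrays, with least squares solved exactly for each pattern of missing values, followed by the empirical Bayes moderation of limma. Each group mean was tested against 0, and contrasts compared HE7L with GLB1 per setting, hypoxic with not hypoxic arrays per construct and tissue, and the means of the 4 settings, 19 comparisons in all. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Errors of log2 values are standard errors (SE) of the fit unless named SD. No array set hypoxic against untreated RNA, so the response to hypoxia itself was not measured.

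Genes named in the text followed a rule set before the data were examined: up to 12 largest increases and 12 largest decreases per comparison among named genes past the threshold with the same sign on every array of the group, or of the group mean in all 4 settings, up to 4 members per gene list, and the 3 of lowest p on each side where fewer than 6 genes passed. Gene lists were written as loci before the data were examined, and 6 more lists were added afterwards, since few members of the first were measured: cytosolic ribosomal proteins, class III peroxidases, core and linker histones, the mitochondrial respiratory chain, proteasome subunits, and a wider list of photosynthesis and photorespiration. The 9 lists with at least 5 measured members were tested in each comparison with camera of limma at its preset inter-gene correlation of 0.01, adjusted over all 171 tests, and again with an estimated correlation and with fry. Of the preset lists, those on haemoglobins, heat shock proteins, jasmonate, nitrate assimilation and the circadian clock had 0 measured members, those on ethylene, iron and haem, pathogen defence and root markers had 1, those on cell wall growth and on cold, drought and abscisic acid had 2, and that on photosynthesis as a shoot marker had 4.

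The fit was tested on simulated data with the residual spread of 11424 genes and 100 changed genes per size. In shoots with 4 replicates, 84 of 100 changes of 0.5 on the log2 scale and 95 of 100 changes of 1 were recovered, and the contrast of both constructs in shoots recovered 65 and 87. For changes of 0.5, 69 of 100 were recovered in HE7L roots with 2 replicates and 54 of 100 in the contrast in hypoxic shoots; recovery is given for 7 of the 19 comparisons, and contrasts in roots, of larger SE, are not among them. The largest number of unchanged genes called in a comparison was 18. These simulated arrays had equal spread, unlike the measured ones. In a further run with each array at its own spread and no changed genes, 2 were called over all 19 comparisons. Both runs drew genes independently, so neither covers shifts that many genes share on 1 array. Alternatives covered the dye flag and dye term, scaling, the arrays in the fit, single probes, missing values, array weights, a replicate block and leaving out each array in turn. Arrays give no counts, and their number limits the precision. Spot intensities were not analysed here. Figures were drawn with matplotlib (version 3.10.9).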

Results

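The series held 25 two-colour arrays of Arabidopsis thaliana, titled as a study of hypoxic stress. Each array compared plants over-expressing GLB1, the class 1 haemoglobin, or HE7L, its mutated form, with plants carrying the empty vector. The GLB1 groups were roots with 3 arrays, hypoxic roots with 3, shoots with 4 and hypoxic shoots with 3, and the HE7L groups were roots with 2 arrays, hypoxic roots with 3, shoots with 4 and hypoxic shoots with 3. A mirror-image pair of GLB1 roots counted as 1 replicate, so 24 arrays entered the tests and n = 2 in GLB1 roots. An array held between 12866 and 13824 values, and the SD of its log2 ratios ran from 0.14 to 0.45. Between 9.82% and 11.92% of the values of an array were exactly 0. The 5 arrays of widest spread in the tests were GLB1 roots replicates 2 and 3 merged, HE7L shoots replicate 3, GLB1 shoots replicate 1, HE7L hypoxic roots replicate 1 and HE7L hypoxic shoots replicate 2. Higher and lower below mean higher and lower in the over-expressor than in the empty vector control. Coordinates are on the TAIR10.1 assembly.

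Over the 4 settings of GLB1 (roots, hypoxic roots, shoots and hypoxic shoots), the comparison asked which transcripts differed from the empty vector in the mean of all settings. AT5G56070 (chromosome 5, 22708679 to 22709204) was 4.69-fold higher, with a log2 ratio of 2.23 ± 0.11 (SE, n = 12, adjusted p = 6.83e-10). AT3G12000 (chromosome 3, 3818046 to 3819642) was 3.10-fold higher, 1.63 ± 0.11 (adjusted p = 6.13e-08), and AT5G56100 (chromosome 5, 22716917 to 22717849) was 2.03-fold higher, 1.02 ± 0.08 (adjusted p = 5.52e-07). RR22, a response regulator on chromosome 3 (1129862 to 1131099), was 1.38-fold higher, 0.47 ± 0.06 (adjusted p = 0.000416). AT3G02840 was higher by 0.34 ± 0.04 on the log2 scale (adjusted p = 3.19e-05) and LBD16, a LOB-domain gene of lateral roots, by 0.21 ± 0.04 (adjusted p = 0.00495). Among named genes below 0 in all 4 settings, AT5G46060 had the largest decrease, -0.27 ± 0.04 (adjusted p = 0.00102), and it lay at or below 0 on 24 of 24 arrays of both constructs. ENOC, a cytosolic enolase on chromosome 2 (12646560 to 12650184), was 1.15-fold lower, -0.20 ± 0.03 (adjusted p = 0.00428). These 8 genes passed with each of the 12 arrays left out in turn. The correlations over all probes leave the direction of 2 of the GLB1 arrays open. With GLB1 hypoxic shoots replicate 2 turned none of the 8 passed (AT5G56070 adjusted p = 0.0741, AT3G12000 0.098), and with GLB1 roots replicates 2 and 3 turned LBD16 (0.171), AT5G46060 (0.351) and ENOC (0.193) did not. On GLB1 hypoxic shoots replicate 2 AT5G56070 was at 2.53 in the direction used. Turning that array sets this value against the other arrays and raises the SE of AT5G56070 from 0.11 to 0.34. Such a loss does not test whether the gene changed.

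In this mean of GLB1, 65 genes or unnamed probes were higher and 38 lower of 12120 tested, of which 31 and 28 were named genes. The 103 calls became 48 without GLB1 hypoxic roots replicate 2, 63 without GLB1 roots replicates 2 and 3, 1355 without GLB1 roots replicate 1, 60 without GLB1 shoots replicate 3, and 63, 61 and 61 without GLB1 hypoxic shoots replicates 1, 2 and 3. They became 4 with the sign of GLB1 hypoxic shoots replicate 2 turned, 36 with that of GLB1 roots replicates 2 and 3 turned, 0 with values as deposited, 156 without the dye term, 200 with arrays scaled to equal spread, 25 with only the GLB1 arrays, 37 with array weights and 421 with the mirror-image arrays as 2 replicates. In the direction used, 43 of the 59 named genes called had their probes in 1 stretch of the probe order. The stretch held 1891 of the 5238 named genes. The share was not computed with an array turned.

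Over the 4 settings of HE7L, the same leading genes were higher. Both constructs were set against empty vector plants, so they are not independent evidence for these genes. A difference of the control cannot be told apart here from one of the over-expressors. Whether control RNA was shared between arrays is not given in the sources used here. AT5G56070 was 5.01-fold higher (adjusted p = 2.21e-10), AT3G12000 3.61-fold (log2 1.85 ± 0.11, n = 12, adjusted p = 4.85e-09) and AT5G56100 was higher by 1.08 ± 0.08 on the log2 scale (adjusted p = 1.47e-07). RR22 was 1.46-fold higher, 0.54 ± 0.06 (adjusted p = 4.45e-05), and AT3G02840 was higher by 0.29 ± 0.04 (adjusted p = 0.000136). AT5G56070, AT3G12000, AT5G56100, RR22 and AT3G02840 each lay above 0 on 24 of 24 arrays of both constructs, and each passed here with any of the 12 HE7L arrays left out. Among named genes below 0 in all 4 settings, AT2G38950 had the largest decrease, -0.36 ± 0.06 (adjusted p = 0.00784), a call lost without HE7L roots replicate 3 (adjusted p = 0.0635) or replicate 1 (adjusted p = 0.0584).

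In this mean of HE7L, 146 genes or unnamed probes were higher and 77 lower of 12087 tested, of which 73 and 43 were named genes. The 223 calls became 28 without HE7L roots replicate 3, 49 without HE7L roots replicate 1, 143 without HE7L hypoxic roots replicate 1, and 116, 142 and 117 without HE7L hypoxic shoots replicates 1, 2 and 3. There were 37 with the sign of HE7L hypoxic roots replicate 1 turned, 54 with that of HE7L hypoxic shoots replicate 2, and 124 and 86 with that of HE7L shoots replicates 3 and 4, 0 with values as deposited, 30 with only the HE7L arrays, 451 without the 5 arrays of widest spread and 1483 with array weights. With HE7L hypoxic roots replicate 1 turned, RR22 (adjusted p = 0.0681), AT3G02840 (0.0511) and AT2G38950 (0.206) did not pass, nor did they with HE7L hypoxic shoots replicate 2 turned (0.0734, 0.0519 and 0.0559), nor AT2G38950 with HE7L shoots replicate 3 or 4 turned (0.196 and 0.0724). In the direction used, 82 of the 116 named genes called lay in the same stretch of the probe order, with 1874 of 5218 named genes. This share too was not computed with an array turned. Of the 43 named genes that were lower, 31 lay on chromosome 5, which carried 28.4% of the named genes tested (two-sided Fisher exact p = 3.25e-09). With 1 array turned, the numbers on chromosome 5, again with two-sided Fisher exact tests, were 8 of 10 (HE7L hypoxic roots replicate 1, exact p = 0.00107), 1 of 1 (HE7L hypoxic shoots replicate 2, p = 0.284), and 22 of 43, 34 of 39 and 13 of 19 (HE7L shoots replicates 1, 3 and 4, p = 0.00183, 2.44e-14 and 0.000338).

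**Figure D1:**
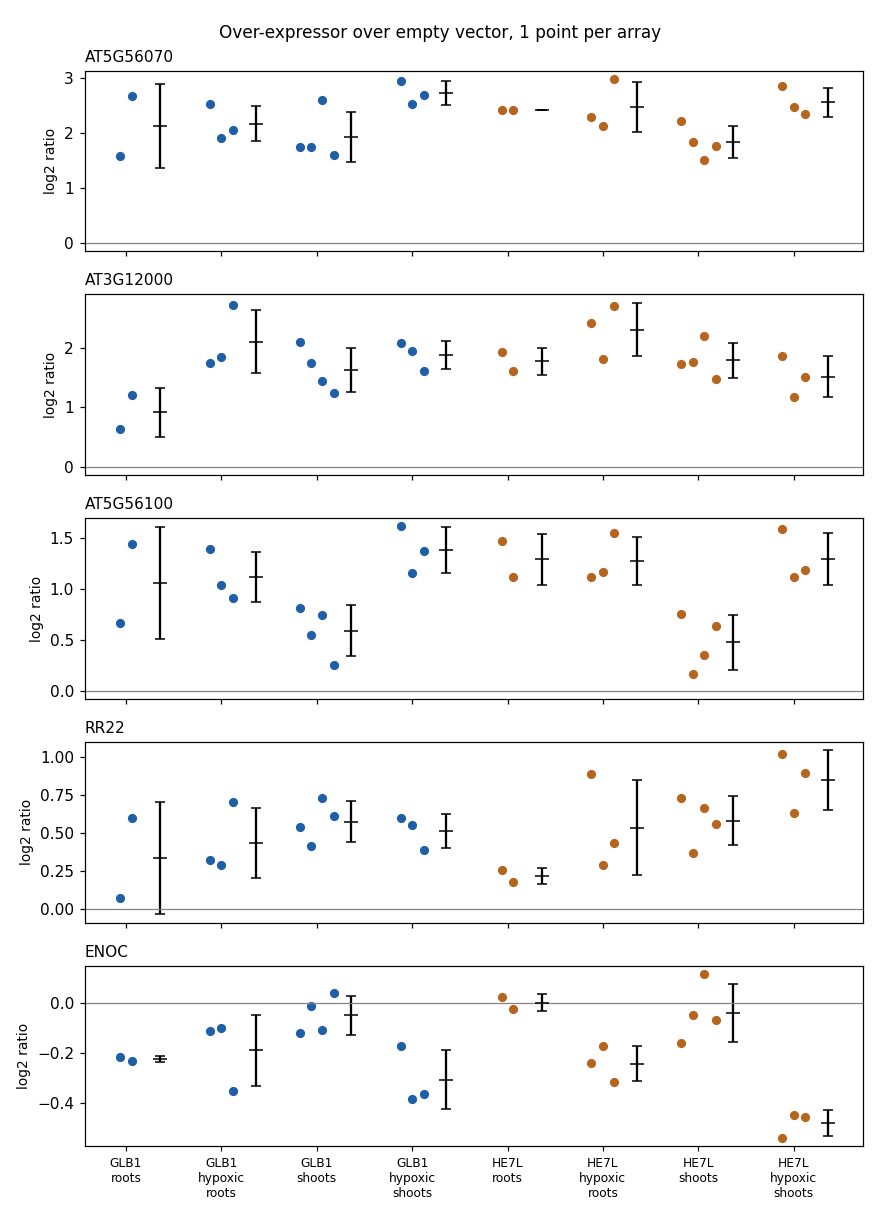
Log2 ratio over the empty vector of AT5G56070, AT3G12000, AT5G56100, RR22 and ENOC on each array (points) in the 8 groups, with the group mean and SD; GLB1 groups are blue and HE7L groups brown. AT5G56070 lies between 1.52 and 2.99 on the 24 arrays, and RR22 between 0.07 and 1.02.

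GLB1 roots (n = 2) were compared with empty vector roots without hypoxia. AT5G56070 was 4.34-fold higher (SE of the log2 ratio 0.26, adjusted p = 0.00184), and it passed with either array left out. EXPB1, an expansin of the cell wall on chromosome 2 (8940833 to 8942706), was higher by 1.07 ± 0.18 on the log2 scale (adjusted p = 0.0311), and AT4G39680 was 1.61-fold higher, 0.69 ± 0.10 (adjusted p = 0.006). D2HGDH, a D-2-hydroxyglutarate dehydrogenase, was 1.32-fold lower, -0.40 ± 0.08 (adjusted p = 0.0444). In total 30 were higher and 16 lower of 12146 tested, including 11 and 10 named genes. The calls of EXPB1 (adjusted p = 1), AT4G39680 (0.616) and D2HGDH (1) ended without the merged replicates 2 and 3, where the 46 calls became 3, against 2151 without replicate 1. With the merged array turned AT5G56070 (0.49 on the log2 scale, adjusted p = 0.743), EXPB1 (-0.55, 0.348), AT4G39680 (-0.31, 0.393) and D2HGDH (0.15, 0.588) did not pass, and EXPB1, AT4G39680 and D2HGDH changed sign. The calls became 3 in that setting, 2 with arrays scaled to equal spread, 0 with array weights, 12 with the 5 arrays of widest spread left out, 93 without the 2 arrays that stood apart (GLB1 shoots replicate 1 and HE7L hypoxic roots replicate 1), 14 with exact zeros taken as missing and 3059 with the mirror-image arrays as 2 replicates. With values as deposited, or with only the arrays of 1 group in the fit, each of the 8 groups had 0 calls. When arrays were scaled to equal spread, AT5G56070 (adjusted p = 0.153) and D2HGDH (0.137) no longer passed. With exact zeros taken as missing AT4G39680 (0.0533) and D2HGDH (0.118) did not. With array weights none of the named genes passed, AT5G56070 having an adjusted p of 0.414. Both arrays of this group got the same weight (0.339), so the weights cannot tell the wide merged array from replicate 1.

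In GLB1 hypoxic roots (n = 3), AT5G56070 was 4.47-fold higher (2.16 ± 0.21, adjusted p = 1.9e-05), AT3G12000 4.30-fold (adjusted p = 1.9e-05) and AT5G56100 2.14-fold (log2 SE 0.15, adjusted p = 0.00174), and these 3 passed with each array left out. AT1G26920 was 1.66-fold lower, -0.73 ± 0.12 (adjusted p = 0.0079). VCS, a scaffold of mRNA decapping, was 1.36-fold lower, -0.44 ± 0.09 (adjusted p = 0.0406). Its value averages probes whose mean log2 ratios over all arrays were -0.0016 and -0.175. Their separate means in this group are not given here. In total 24 were higher and 16 lower of 12161, including 12 and 4 named genes. Both decreases ended without replicate 2 (AT1G26920 adjusted p = 0.098, VCS 0.425) or replicate 3 (0.194 and 0.414), and that of VCS also with exact zeros taken as missing (0.0913). The 40 calls became 69 without replicate 1 and 11 without replicate 2 or replicate 3. Scaled arrays gave 119, array weights 640, leaving out the 5 arrays of widest spread 466, leaving out the 2 that stood apart 88, and exact zeros as missing 23.

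In GLB1 shoots (n = 4), AT5G56070 was 3.80-fold higher (adjusted p = 3.35e-05) and AT3G12000 3.09-fold higher (1.63 ± 0.18, adjusted p = 0.000189). With an unnamed probe they were the 3 calls of 12142 tested, all higher, and all 3 remained without any 1 of the 4 arrays; 742 had an unadjusted p under 0.05. RR22 did not pass (0.57 ± 0.10, adjusted p = 0.063), nor did AT5G56100 (0.59 ± 0.13, adjusted p = 0.23). The 3 calls became 5 without replicate 1 or without replicate 3, 5 without the dye term, with the mirror-image arrays as 2 replicates or without the 2 arrays that stood apart, 11 with scaled arrays, 34 without the 5 arrays of widest spread and 55 with array weights.

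In GLB1 hypoxic shoots (n = 3), AT5G56070 was 6.56-fold higher (2.71 ± 0.21, adjusted p = 1.51e-06), AT3G12000 3.68-fold (1.88 ± 0.21, adjusted p = 0.000206) and AT5G56100 2.58-fold (1.37 ± 0.15, adjusted p = 0.000206), in each leave-out as well. AT5G48770 was 1.33-fold lower, -0.41 ± 0.07 (adjusted p = 0.0139), a call lost without replicate 2 (adjusted p = 0.301) or replicate 3 (0.31). In total 13 were higher and 2 lower of 12149, including 5 and 1 named genes. The 15 calls became 0 with replicate 2 turned, AT5G56070 then being at 1.02 (adjusted p = 1). They became 7, 4 and 5 without replicates 1, 2 and 3, 30 with scaled arrays, 25 without the 5 arrays of widest spread and 68 with array weights.

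In HE7L roots (n = 2), AT5G56070 was 5.38-fold higher (2.43 ± 0.25, adjusted p = 0.000101), also with either array left out. AT3G12000 was 3.43-fold higher (1.78 ± 0.25, adjusted p = 0.00522) and AT1G27900 1.37-fold higher (0.46 ± 0.07, adjusted p = 0.00808). In total 8 were higher and 0 lower of 12124 by limma, including 4 named genes; 885 had an unadjusted p under 0.05. AT3G12000 lost its call without replicate 3 (adjusted p = 0.861) or replicate 1 (0.0959), and AT1G27900 likewise (0.977 and 0.0959) and with exact zeros taken as missing (0.107). The 8 calls became 2 without replicate 3 and 3 without replicate 1, but 212 with scaled arrays, 283 without the 5 arrays of widest spread, 899 with array weights and 13 with the mirror-image arrays as 2 replicates.

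In HE7L hypoxic roots (n = 3), AT5G56070 was 5.52-fold higher (2.46 ± 0.21, adjusted p = 7.32e-06), AT3G12000 higher by 2.31 ± 0.21 (adjusted p = 8.83e-06) and AT5G56100 2.40-fold (1.26 ± 0.15, adjusted p = 0.000337), in each leave-out as well. HBT, a subunit of the anaphase-promoting complex, was 1.25-fold higher, 0.33 ± 0.06 (adjusted p = 0.025). In total 30 were higher and 6 lower of 12159, including 9 and 1 named genes. HBT did not pass without replicate 2 (adjusted p = 0.0732) or replicate 3 (0.169), and with scaled arrays AT5G56070 (0.0708), AT5G56100 (0.0736) and HBT (0.0703) did not. The 36 calls became 21, 97 and 14 without replicates 1, 2 and 3, and 0 with the sign of replicate 1 turned, where AT5G56070 had an adjusted p of 0.719, AT3G12000 of 0.771 and AT5G56100 of 0.716. There were 15 with scaled arrays, 70 without the dye term, 68 with each probe tested singly, 89 with the mirror-image arrays as 2 replicates, 117 without the 5 arrays of widest spread and 125 with array weights.

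In HE7L shoots (n = 4), AT5G56070 was 3.57-fold higher (1.83 ± 0.18, adjusted p = 4.31e-05) and AT3G12000 3.47-fold (1.79 ± 0.18, adjusted p = 4.31e-05), in each leave-out as well. RR22 was higher by 0.58 ± 0.10 on the log2 scale (adjusted p = 0.0315), and scpl42, a serine carboxypeptidase-like gene, 1.23-fold, 0.30 ± 0.05 (adjusted p = 0.0363). In total 9 were higher and 0 lower of 12130 by limma, including 4 named genes; 793 had an unadjusted p under 0.05. Without replicates 1, 2, 3 and 4 in turn, the adjusted p of RR22 was 0.0866, 0.0649, 0.326 and 0.193, and that of scpl42 was 0.0812, 0.32, 0.246 and 0.218. With scaled arrays AT5G56070 (0.182), RR22 (0.195) and scpl42 (0.349) did not pass, nor did scpl42 without the dye term (0.0551). The 9 calls became 17, 3, 5 and 3 without replicates 1, 2, 3 and 4, 17 without the 2 arrays that stood apart and 114 with array weights. With the sign of replicate 1, 3 or 4 turned there were 2, 0 and 0, and AT5G56070 (adjusted p = 0.403, 0.518 and 0.919) and AT3G12000 (0.287, 0.607 and 0.919) did not pass.

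In HE7L hypoxic shoots (n = 3), AT5G56070 was 5.96-fold higher (2.57 ± 0.21, adjusted p = 3.6e-06), AT5G56100 2.47-fold (1.31 ± 0.15, adjusted p = 0.000603) and RR22 1.79-fold (0.84 ± 0.12, adjusted p = 0.00149). RCA, the activase of Rubisco, was 1.30-fold higher, 0.38 ± 0.07 (adjusted p = 0.0161), and CHL, a lipocalin of the chloroplast, 1.53-fold, 0.61 ± 0.14 (adjusted p = 0.0312). ENOC was 1.39-fold lower, -0.47 ± 0.06 (adjusted p = 0.00149), and the expansin gene EXPA20 1.37-fold lower, -0.46 ± 0.09 (adjusted p = 0.0172). In total 121 were higher and 50 lower of 12159, including 36 and 26 named genes. AT5G56070, AT5G56100, RR22 and ENOC passed with each array left out. Without replicate 2, RCA (adjusted p = 0.45), CHL (0.77) and EXPA20 (0.49) did not pass, nor did RCA (0.062) and CHL (0.0946) without replicate 3, or RCA (0.067) and CHL (0.0544) without the dye term. CHL also missed the threshold with exact zeros taken as missing (0.0548). With the sign of replicate 2 turned there were 0 calls, AT5G56070 being at 0.96, RR22 at 0.43 and ENOC at -0.16 (adjusted p = 1 for each). The 171 calls became 11 without replicate 2 and 23 without replicate 3, 38 without the 5 arrays of widest spread, 88 with exact zeros as missing, 274 without the 2 arrays that stood apart and 2917 with array weights.

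HE7L was compared with GLB1 in each setting, which asks whether the mutated form acted differently from the haemoglobin itself. No gene passed in limma: the counts were 0 of 12110 in roots, 0 of 12159 in hypoxic roots, 0 of 12127 in shoots, 0 of 12147 in hypoxic shoots and 0 of 12068 in the mean of the 4 settings. At an unadjusted p under 0.05 there were 732, 422, 332, 1021 and 358. EXPB1 differed by -1.003 ± 0.25 in roots (adjusted p = 0.794), ZW9 by -1.03 ± 0.24 in shoots (adjusted p = 0.962) and RCA by 0.44 ± 0.10 in hypoxic shoots (adjusted p = 0.216), and AT1G26920 was 0.60 ± 0.17 in hypoxic roots (adjusted p = 0.984). In the mean of the settings AT1G27900 differed by 0.20 ± 0.04 and MMT, a methionine S-methyltransferase, by -0.17 ± 0.05 (adjusted p = 0.935 for both). In roots 1 gene passed without GLB1 roots replicates 2 and 3 and 943 without GLB1 roots replicate 1; in hypoxic roots 2 passed without GLB1 replicate 1 and 1 without HE7L replicate 2. In the mean 1 passed without GLB1 roots replicates 2 and 3, and 5 without GLB1 roots replicate 1. The answer in hypoxic shoots depends on the fit: 600 genes or unnamed probes passed with only the arrays of both groups, 443 with array weights, 1 with exact zeros taken as missing and 1 with GLB1 hypoxic shoots replicate 2 turned. With the 5 arrays of widest spread left out, 1 passed in roots and 1 in the mean.

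Hypoxic and not hypoxic arrays of 1 construct and tissue were compared, which asks whether the difference from the empty vector changed under hypoxia. The counts in limma were 0 of 12144 in GLB1 roots, 0 of 12139 in GLB1 shoots, 0 of 12120 in HE7L roots and 0 of 12128 in HE7L shoots, against 1344, 321, 676 and 1663 at an unadjusted p under 0.05. In HE7L shoots, ENOC was lower under hypoxia by -0.43 ± 0.08 (adjusted p = 0.0743) and ALDH3F1, an aldehyde dehydrogenase, higher by 0.57 ± 0.12 (adjusted p = 0.102), neither past the threshold. HBT differed by 0.40 ± 0.10 in HE7L roots (adjusted p = 0.616), AT4G39680 by -0.71 ± 0.12 in GLB1 roots (adjusted p = 0.0975) and AT5G48770 by -0.49 ± 0.09 in GLB1 shoots (adjusted p = 0.407). In GLB1 roots 5 passed without hypoxic replicate 1, 1 without replicates 2 and 3, and 1461 without replicate 1. In HE7L roots 1 passed without hypoxic replicate 2, and in HE7L shoots 1 without replicate 3 of the arrays that were not hypoxic. With array weights 149 passed in HE7L roots, 1224 in HE7L shoots and 1 in GLB1 shoots, and with the 5 arrays of widest spread left out 116 in HE7L roots and 2 in GLB1 roots. Scaling arrays to equal spread gave 1 in GLB1 roots and 2 in HE7L roots, counting the mirror-image arrays as 2 replicates gave 318 in GLB1 roots, and turning the sign of HE7L shoots replicate 1 or 3 gave 5 or 1 in HE7L shoots.

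Of the lists written beforehand, the core hypoxia-responsive genes were called in GLB1 shoots, where 10 of 10 measured members lay above 0 with a median of 0.23 (camera adjusted p = 0.00997, 0.879 with an estimated correlation). PDC2, a pyruvate decarboxylase, was at 0.15 ± 0.11 there, and the largest member, AT4G27450, at 0.64 ± 0.31; 0 of the 10 passed in limma over all genes and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Their median was 0.93 on GLB1 shoots replicate 1 and -0.18, 0.18 and 0.02 on the other 3 arrays, and the adjusted p was 0.81 without replicate 1. In the contrast of hypoxic and other GLB1 shoots their median was -0.24 (adjusted p = 0.0307, 0.879 with an estimated correlation), and 0.991 without replicate 1. It was 0.236 and 0.0515 without GLB1 hypoxic shoots replicates 2 and 3, 0.0645 without GLB1 roots replicates 2 and 3, 0.0559 without HE7L hypoxic shoots replicate 2, and 0.282 with GLB1 hypoxic shoots replicate 2 turned. Glycolysis and fermentation, with 6 members, had no call (lowest adjusted p = 0.232, in GLB1 hypoxic roots); its member GAPC2, a glyceraldehyde-3-phosphate dehydrogenase, was at 0.30 ± 0.07 there and passed adjusted over the list alone, not over all genes (adjusted p = 0.0995). Antioxidant enzymes, with 5 members, had no call either (lowest adjusted p = 0.371).

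For smaller lists the members stand alone. RCA of the photosynthesis markers passed over all genes in HE7L hypoxic shoots, and 2 of the 4 members did adjusted over the list alone; the median of the 4 was 0.545 on replicate 2 there, against 0.05 and 0.16 on the other arrays. The other 3 were LHB1B2, LHCB4.1 and PSAN, with lowest adjusted p of 0.11, 0.335 and 0.622 over the 8 groups. EIN3, the ethylene transcription factor, was at 0.25 in GLB1 hypoxic roots (adjusted p = 0.42, and 0.0253 unadjusted as the 1 member of its list), GSA1 of haem synthesis at -0.17 in HE7L hypoxic shoots (0.357), and PDF1.2 of defence at -0.26 in HE7L hypoxic roots (0.676). The expansins EXPA7 and EXPA8 were at -0.34 (0.169) and 0.33 (0.252) in GLB1 roots, both past the threshold adjusted over their list of 2 alone, COR47 of the cold response at -0.15 in GLB1 roots (0.343) and KIN2 at 0.17 in HE7L hypoxic shoots (0.668), each where its adjusted p was lowest.

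Among the lists added after the data were seen, cytosolic ribosomal protein genes were called most often. In GLB1 roots 54 of 63 lay above 0, with a median of 0.32 (adjusted p = 2.24e-06), and in GLB1 shoots 49 of 63, with a median of 0.13 (adjusted p = 0.00111). Both calls had an adjusted p of 0.879 with an estimated correlation. In HE7L hypoxic shoots 46 of 63 lay above 0, with a median of 0.10 (adjusted p = 0.0265), and the means of GLB1 and HE7L had medians of 0.09 (adjusted p = 0.000269) and 0.07 (adjusted p = 0.021). These 3 calls too had an adjusted p of 0.879 with an estimated correlation. Each call ended without a single array: the adjusted p was 0.945 in GLB1 roots and 0.515 in the GLB1 mean without GLB1 roots replicates 2 and 3, 0.648 in GLB1 shoots without replicate 1, and 0.984 in HE7L hypoxic shoots and 0.284 in the HE7L mean without hypoxic shoots replicate 2. The call in the HE7L mean also ended without hypoxic roots replicate 2 (0.123), roots replicate 1 (0.117) or shoots replicate 1 (0.0877), yet it held without the 5 arrays of widest spread (0.00686), hypoxic shoots replicate 2 among them, and without the 2 arrays that stood apart (0.0012). With single arrays turned the direction did not hold: with GLB1 roots replicates 2 and 3 turned 8 of 63 lay above 0 in GLB1 roots (median -0.31, adjusted p = 1e-06) and the GLB1 mean had a median of -0.04 (0.0704), and with HE7L hypoxic shoots replicate 2 turned 11 of 63 lay above 0 in that group (median -0.12, 0.000651) and the HE7L mean had an adjusted p of 0.801. The HE7L mean also missed the threshold with HE7L shoots replicate 1 turned (0.129). The leading genes argue against such turns, so these reversals show only how far the list rests on single arrays. The median of the ribosomal list was 0.56 on GLB1 roots replicates 2 and 3 and 0.01 on replicate 1. In limma 0 of the 63 ribosomal genes passed over all genes or adjusted over the list alone in these 5 results; 22, 7, 7, 10 and 9 had an unadjusted p under 0.05, in the order given.

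Genes of the mitochondrial respiratory chain were higher as a list in GLB1 roots, with 16 of 19 above 0 and a median of 0.23 (adjusted p = 0.00429; 0.879 with an estimated correlation). Without replicates 2 and 3 the adjusted p was 0.719, and with them turned 2 of 19 lay above 0 (median -0.23, adjusted p = 0.000147). In HE7L hypoxic roots 18 of 21 class III peroxidases lay above 0 with a median of 0.11 (adjusted p = 0.00901), and genes of photosynthesis and photorespiration had a median of -0.13 (adjusted p = 0.0282). With an estimated correlation the adjusted p of both was 0.879. Without replicate 1 these were 0.326 and 0.376. With replicate 1 turned 8 of 21 peroxidases lay above 0 (adjusted p = 0.485), and the photosynthesis list had a median of 0.07 (0.581). The photosynthesis call in these roots also ended without replicate 3 (0.0625), without GLB1 roots replicates 2 and 3 (0.0581) and without the dye term (0.0827). In HE7L hypoxic shoots 13 of the 16 genes of photosynthesis and photorespiration lay above 0 with a median of 0.19 (adjusted p = 0.00128, 0.879 with an estimated correlation), against 0.126 without replicate 2 and 4 of 16 above 0 with it turned (0.266); RCA passed over all genes and 4 of the 16 adjusted over the list alone. The same list was higher in HE7L than in GLB1 hypoxic shoots, with 15 of 16 above 0 and a median of 0.20 (adjusted p = 0.000366), but not with an estimated correlation (adjusted p = 0.879); with each of the 24 arrays left out it was at most 0.0273, and with HE7L hypoxic shoots replicate 2 turned 5 of 16 lay above 0 (0.765). Core and linker histones and proteasome subunits had no call (lowest adjusted p = 0.141 and 0.334). None of the 21 calls of lists held with an estimated correlation, and fry called none.

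**Figure D2:**
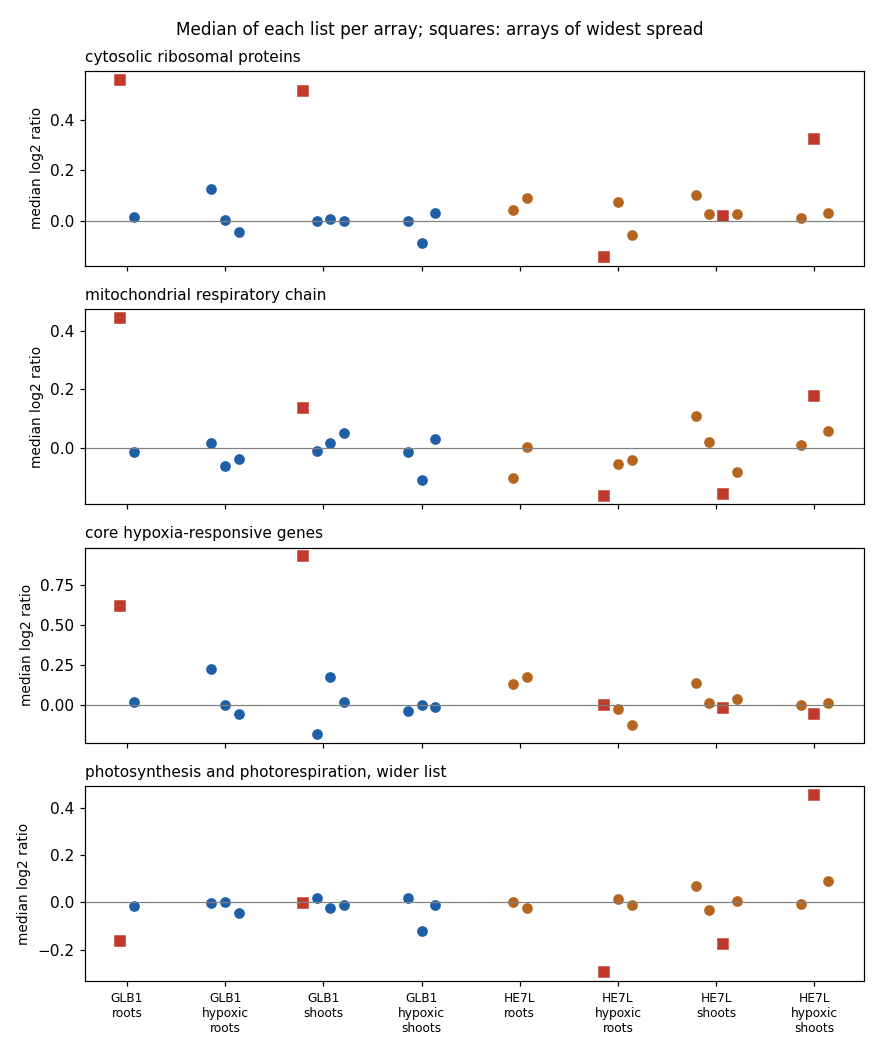
Median log2 ratio over the empty vector of the members of 4 gene lists on each array (points) in the 8 groups; red squares are the 5 arrays of widest spread. The ribosomal median is 0.56 on GLB1 roots replicates 2 and 3 and 0.52 on GLB1 shoots replicate 1, both red squares.

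**Figure D3:**
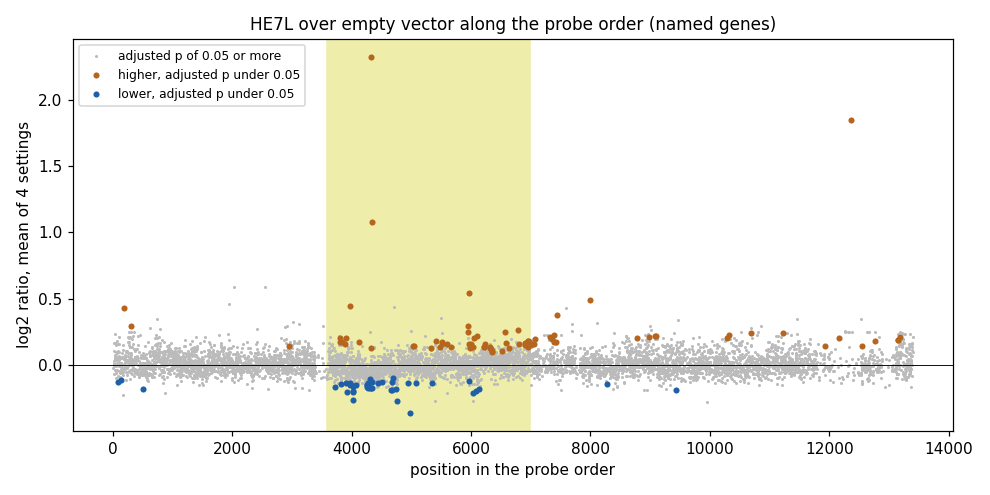
Mean log2 ratio of HE7L over the empty vector for each named gene (vertical axis) against the position of its probe in the probe order (horizontal axis), with genes called higher in brown and lower in blue. The shading runs from position 3579 to 6991, the first and last probe of the stretch; 138 probes between them are not counted in the stretch, and 82 of the 116 called genes have all their probes in it.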

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

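The tests of an exchange of tissue labels, by correlation and by midpoint, were chosen only after the result was seen. Of 39 values tested for a single array far from the other 3 of its group of 4, 7 stood out. The rule flags about 1 in 20 for independent, normally distributed values. These values share arrays and include genes named from the same data, so the 7 do not measure an excess over chance. In GLB1 shoots, replicate 1 had a spread of log2 ratios of 0.42, against 0.15 to 0.16 on the other arrays. The same array had a median of 0.30 over core and linker histones (others -0.02 to 0.03) and of 0.52 over ribosomal protein genes (others 0.00 to 0.01, rounded). AT5G56070 was at 2.60 on GLB1 shoots replicate 3 and between 1.60 and 1.75 on the others. In HE7L shoots, replicate 3 had a spread of 0.45 (others 0.14 to 0.19) and a median of -0.31 over antioxidant enzymes (others 0 to 0.04). Ribosomal protein genes had a median of 0.10 on HE7L shoots replicate 1 and of 0.02 to 0.03 on the others.

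Lists differed between groups by a test of the difference itself in 11 cases, with camera at its preset correlation; none held with an estimated correlation (adjusted p = 0.879 for each). Between HE7L and GLB1 roots, ribosomal protein genes differed by a median of -0.22 (adjusted p = 0.0029) and respiratory chain genes by -0.34 (0.000278). Between hypoxic and other GLB1 roots these lists differed by -0.27 (4.58e-05) and -0.31 (0.00111), and the respiratory chain differed by -0.10 (0.0265) between HE7L and GLB1 in the mean of the settings. Without GLB1 roots replicates 2 and 3 these 5 had adjusted p of 0.202, 0.855, 0.963, 0.949 and 0.963. Between hypoxic and other GLB1 shoots, core hypoxia-responsive genes differed by -0.24 (0.0307) and ribosomal protein genes by -0.12 (0.00382), against 0.991 and 0.964 without GLB1 shoots replicate 1. Between HE7L and GLB1 hypoxic shoots, ribosomal protein genes differed by 0.11 (0.0282), against 0.963 without HE7L hypoxic shoots replicate 2. Genes of photosynthesis and photorespiration differed by 0.20 (0.000366) there, by 0.23 (0.00921) between hypoxic and other HE7L shoots, and by 0.093 (0.0183) between HE7L and GLB1 in the mean, against 0.0273, 0.2 and 0.222 without that array; the last was 0.0852 without the dye term. Of the 24 fits with 1 array left out, the last of these held in 19, the respiratory chain in the mean in 17, and ribosomal protein genes in 22 each for HE7L minus GLB1 in roots, in hypoxic shoots, and for hypoxic minus other GLB1 shoots; core hypoxia-responsive genes held in 19. The correlations over all probes alone leave the direction of some arrays open, though the leading genes argue against a wrong sign of these. With GLB1 roots replicates 2 and 3 turned, the ribosomal and respiratory differences were 0.36 (7.7e-07) and 0.23 (0.0371) between HE7L and GLB1 roots, 0.28 (5.96e-05) and 0.18 (0.019) between hypoxic and other GLB1 roots, and 0.06 (0.182) for the respiratory chain in the mean. With HE7L hypoxic shoots replicate 2 turned, the ribosomal difference in hypoxic shoots was -0.12 (0.0137), and those of photosynthesis had adjusted p of 0.765, 0.482 and 0.903. With GLB1 hypoxic shoots replicate 2 turned, core hypoxia-responsive genes (0.282) and ribosomal protein genes (0.421) did not differ past the threshold between hypoxic and other GLB1 shoots, nor did ribosomal protein genes between HE7L and GLB1 hypoxic shoots (0.503).

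GLB1 shoots replicate 1 and HE7L hypoxic roots replicate 1 stood apart from their groups. An exchange of their tissue labels was tested on 50 probes per profile that separate root from shoot arrays: by correlation 1 of the 2 arrays was closer to the other tissue, but only 11 of the 19 remaining arrays were then placed in their own tissue. Judged by the midpoint between both profiles, 2 of the 2 lay on the other tissue's side, at 0.14 for GLB1 shoots replicate 1 and -0.40 for HE7L hypoxic roots replicate 1 (above 0 is the side of roots), and 18 of the 19 remaining arrays lay on their own side. A wide spread of log ratios, whatever the label, is the other explanation: of the 3 other wide arrays, 2 were closer to the other tissue by correlation and 1 lay on the other side of the midpoint. Each array set RNAs of the same tissue against each other. The profiles therefore hold differences from the empty vector, not tissue expression, and cannot show directly which tissue an array held. An exchange and a wide spread cannot be told apart with so few arrays, and no biological explanation was tested.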

How the results depend on the processing

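The alternatives with the mirror-image arrays counted as 2 replicates, with 2 or 5 arrays left out, with exact zeros as missing, with the sign of 1 array turned, and with only the lists fixed beforehand were chosen only after the data were seen. Counts of genes past the threshold are given; except where a sentence names one, the cause was not tested. Of the 20 results, only HE7L minus GLB1 in shoots (0) kept its count within 1.5 times its value under all alternatives. Centring on the median, at least 1 array per group, only genes measured on all arrays, and a replicate block (correlation -0.04, which pairs arrays by replicate number) moved none by more than that. AT5G56070, AT3G12000, AT5G56100 and RR22 passed in the means of both constructs under every alternative tried for named genes: no dye term, scaling, 2 or 5 arrays left out, array weights, the block, exact zeros as missing and each array left out. With the sign of an array turned, AT5G56070, AT3G12000, AT5G56100 and RR22 missed it in the GLB1 mean (GLB1 hypoxic shoots replicate 2; adjusted p = 0.0741, 0.098, 0.101 and 0.128) and RR22 in the HE7L mean (HE7L hypoxic roots replicate 1, 0.0681; HE7L hypoxic shoots replicate 2, 0.0734). With arrays left out, adjusted p values of single genes and lists took genes with at least 1 array per group, and counts took at least 2 where the group had them.

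With values as deposited, the other reading of the dye swap flag, all 8 groups and both means over the empty vector had 0. If the ratios follow the channels, real differences cancel there between arrays of opposite flags. The 0 then does not test the calls. Without the dye term GLB1 shoots had 5, HE7L hypoxic roots 70 and the GLB1 mean 156. With arrays scaled to equal spread, GLB1 roots had 2, GLB1 hypoxic roots 119, GLB1 shoots 11, GLB1 hypoxic shoots 30, HE7L roots 212, HE7L hypoxic roots 15, hypoxic minus not hypoxic in GLB1 roots 1 and in HE7L roots 2, and the GLB1 mean 200. With only the arrays of the groups compared, so fewer arrays, each of the 8 groups had 0, HE7L minus GLB1 in hypoxic shoots 600, the GLB1 mean 25 and the HE7L mean 30. With each probe tested singly HE7L hypoxic roots had 68.

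Array weights ran from 0.148 to 6.11, and their estimation stopped before it converged. With array weights GLB1 roots had 0, GLB1 hypoxic roots 640, GLB1 shoots 55 and GLB1 hypoxic shoots 68. HE7L roots had 899, HE7L hypoxic roots 125, HE7L shoots 114 and HE7L hypoxic shoots 2917. HE7L minus GLB1 in hypoxic shoots had 443, the GLB1 mean 37 and the HE7L mean 1483. Hypoxic minus not hypoxic had 1 in GLB1 shoots, 149 in HE7L roots and 1224 in HE7L shoots. In groups of 2 arrays both got the same weight, 0.339 in GLB1 roots and 1.902 in HE7L roots. The weighted counts of these groups therefore do not show how calls depend on the spread of single arrays.

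With the mirror-image arrays as 2 replicates, GLB1 roots had 3059, GLB1 shoots 5, HE7L roots 13, HE7L hypoxic roots 89, hypoxic minus not hypoxic GLB1 roots 318 and the GLB1 mean 421. If both arrays are the same hybridization, it then counts as 2 replicates. With GLB1 shoots replicate 1 and HE7L hypoxic roots replicate 1 left out, GLB1 roots had 93, GLB1 hypoxic roots 88, GLB1 shoots 5, HE7L shoots 17 and HE7L hypoxic shoots 274. With the 5 arrays of widest spread left out, GLB1 roots had 12, GLB1 hypoxic roots 466, GLB1 shoots 34, GLB1 hypoxic shoots 25, HE7L roots 283, HE7L hypoxic roots 117, HE7L hypoxic shoots 38, HE7L minus GLB1 in roots 1, hypoxic minus not hypoxic 2 in GLB1 roots and 116 in HE7L roots, the HE7L mean 451, HE7L minus GLB1 in the mean 1, and the gene lists 11 calls. With exact zeros as missing, GLB1 roots had 14, GLB1 hypoxic roots 23, HE7L hypoxic shoots 88 and HE7L minus GLB1 in hypoxic shoots 1. With the sign of an array turned, GLB1 roots had 3 and the GLB1 mean 36 (GLB1 roots replicates 2 and 3), HE7L hypoxic roots 0 and the HE7L mean 37 (HE7L hypoxic roots replicate 1), HE7L shoots 2 and hypoxic minus not hypoxic HE7L shoots 5 (HE7L shoots replicate 1), these 0 and 1 and the HE7L mean 124 (HE7L shoots replicate 3), HE7L shoots 0 and the HE7L mean 86 (HE7L shoots replicate 4), HE7L hypoxic shoots 0 and the HE7L mean 54 (HE7L hypoxic shoots replicate 2), and GLB1 hypoxic shoots 0, HE7L minus GLB1 in hypoxic shoots 1 and the GLB1 mean 4 (GLB1 hypoxic shoots replicate 2). The 21 calls of gene lists became 0 with an estimated correlation, 0 with fry and 1 with only the lists fixed beforehand.

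With each array of the groups compared left out in turn, not those of other groups in the same fit, counts ran from 3 to 2151 in GLB1 roots, 11 to 69 in GLB1 hypoxic roots, 3 to 5 in GLB1 shoots, 4 to 7 in GLB1 hypoxic shoots, 2 to 3 in HE7L roots, 14 to 97 in HE7L hypoxic roots, 3 to 17 in HE7L shoots and 11 to 254 in HE7L hypoxic shoots. HE7L minus GLB1 ran from 0 to 943 in roots, 0 to 2 in hypoxic roots, and 0 to 0 in shoots and in hypoxic shoots. Hypoxic minus not hypoxic ran from 0 to 1461 in GLB1 roots, 0 to 0 in GLB1 shoots, and 0 to 1 in HE7L roots and in HE7L shoots. The GLB1 mean ran from 48 to 1355, the HE7L mean from 28 to 282, their difference from 0 to 5, and the calls of gene lists, with each of all 24 arrays left out, from 10 to 27. The array behind each change by over 1.5 times is named beside its comparison; the 254 came without HE7L hypoxic shoots replicate 1 and the 282 without HE7L shoots replicate 1. For the lists the 10 came without GLB1 roots replicates 2 and 3 and the 27 without GLB1 roots replicate 1 or HE7L shoots replicate 3. Where a group was left with 1 array, that array is assumed to vary like the other groups. Signal over background was not analysed here, so its effect on weak spots is not known.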

Other observations

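The tests on chromosome 5, on the place in the probe order and on other splits of the arrays were chosen only after the result was seen; those on signal carried between spots and on linked genes were not. GLB1 shoots replicate 1 and HE7L shoots replicate 1 held a value for all 13824 probes, while each other array lacked between 424 and 958.

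The largest ratios lay close together in the probe order. Of 32 probes with a mean log2 ratio above 0.4, 16 fell in 4 runs of at least 3 probes within 12 places, against at most 6 in 10000 random placings. AT5G56100 lay 4 places after AT5G56070, and AT3G12000 lay 7 places after an unnamed probe with a mean of 2.09. Signal carried from a spot to those printed after it may be a source: 7 of 12 raised neighbours tracked the strongest probe of their own run best over arrays, and 8 lay after it and 4 before. AT5G56100 was among these 7 and AT3G12000 was not; the 24 arrays come from 8 groups, and no p was computed for this tracking. A linked difference of the genome around AT5G56070 could be measured on 1 neighbour alone, TEX1, whose mean log2 ratio had a size of 0.0281, while 3 genes lie between AT5G56070 and AT5G56100. Neither explanation can be told apart from a change of expression of these genes, since raised probes lay on both sides and only 1 neighbour was measured.

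Most named genes lower in the mean of HE7L lay on chromosome 5. A change along that chromosome is argued against by its probes: 30 of its 702 genes inside a stretch of the probe order, where at least 60% of the 50 surrounding named probes lie on 1 chromosome, were lower, against 1 of 750 outside it (two-sided Fisher exact p = 5.06e-09). The place in the probe order is a candidate explanation for calls in either direction. Of genes on the other chromosomes, 43 of 1172 inside the stretch were called, against 26 of 2482 outside it (two-sided Fisher exact p = 2.86e-07). Lower genes alone numbered 3, 3, 6 and 0 on chromosomes 1, 2, 3 and 4, inside or outside the stretch. The stretch as a whole therefore does not account for the excess of lower genes on chromosome 5. In the mean of GLB1, 19 of 706 genes of chromosome 5 were lower inside it and 1 of 752 outside (p = 1.16e-05), and 16 of 1185 other genes were called inside and 12 of 2483 outside (p = 0.0074, both by Fisher's exact test). Which feature of that place matters, such as signal, plate or kind of probe, was not tested, and genes are not independent replicates. The counts inside and outside the stretch are in the direction used and were not made with an array turned.

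For counts of genes past the threshold, signs of arrays were flipped or groups split anew, the real pattern included. For the directions used, 1 of 100 sign patterns drawn gave as many as the real 103 in the GLB1 mean, and the highest other gave 36. In the HE7L mean 1 of 100 gave as many as 223, and the highest other gave 124. The reading of the flags was chosen because these same arrays correlated better under it. The real pattern was thus favoured, and chance is not excluded. By the correlations over all probes alone the direction of 7 arrays is open. AT5G56070, AT3G12000, AT5G56100, RR22 and AT3G02840 lay above 0 on each of them, which argues against a wrong sign there. Turning HE7L shoots replicate 1, a pattern not among those drawn, gave 216. Too few patterns for a share under 0.05 exist for GLB1 hypoxic roots (real 40, highest other 0), GLB1 shoots (3, 0), GLB1 hypoxic shoots (15, 0), HE7L hypoxic roots (36, 0), HE7L shoots (9, 2) and HE7L hypoxic shoots (171, 0), with 4 or 8 patterns each, of which 1 gave as many. The same holds for HE7L minus GLB1 in hypoxic roots (0, 4) and hypoxic shoots (0, 1), with 10 splits each. Where the real count is 0, every split gives as many, so the splits do not test chance for HE7L minus GLB1 in shoots (35 splits, highest other 2), hypoxic minus not hypoxic in GLB1 shoots and in HE7L shoots (35 splits each, highest other 0), and HE7L minus GLB1 in the mean (100 splits, highest other 0).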
